A study of Arabidopsis thaliana with 12 samples.

How the data were processed

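Per the labels, total RNA of wild-type Arabidopsis thaliana plants of the Columbia 0 ecotype was profiled by expression array with 1 channel per sample, in 6 light-adapted samples and 6 samples of plants returned to light after 1 h of darkness. The recovery time is given as 2 h in the titles and descriptions and as 1 h in the source names, and nothing in the labels settles which is right. The values used are the intensities deposited by the authors, 1 table of 3439 features by 12 samples, with values from 0 to a ceiling of 100. They were taken here as linear intensities because they are never negative and include exact zeros, and every log2 difference below rests on that reading. The scanner, the background correction, the normalization and the meaning of the ceiling are not given in the sources used here, so the scale and any centring of the deposited intensity values stay unknown. As the values have 1 channel, no orientation of a ratio had to be assumed, but the signs of some differences below depend on the scaling. The labels do not say whether the replicates came from separate plants or cultures, so the p-values measure only the spread between these samples, which may be technical.

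The deposited median intensity of light-adapted arrays 1 to 6 was 0.103, 0.101, 0.0972, 0.103, 0.0710 and 0.0760, and that of recovery arrays 1 to 6 was 0.0363, 0.0374, 0.0358, 0.0367, 0.0379 and 0.0400. Summed intensity per array ran from 2286 to 3314. Depth has no meaning for array values, and the number of arrays limits the precision. Gene names came from the platform annotation supplied with the table, updated through gene identifiers to a reference table of assembly TAIR10.1. Of the 3439 features, 692 have 1 gene in that annotation, 870 have several and 1877 are not named in it. Of the 692, 690 matched the reference table, at 689 loci. No gene is named from a feature with several genes, and no coordinates are given because the build behind the array is not known.

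The tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Intensities were taken to log2 with values at 0 set to missing, and features with at least 4 measured values in each group entered, which left 2364 features, 452 of them with 1 gene, and put aside 1075. Because the array medians differed by more than 10%, the rule fixed for that case applied and the log2 values were quantile normalized. Groups were compared in limma 3.58.1 under R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment, two-sided, and a feature was called at an adjusted p under 0.05. Differences are recovery minus light adapted. Principal components were computed on the 1429 features above 0 on all 12 arrays, and array-level values were compared with exact two-sided permutation tests over all splits into 6 and 6. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

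The rule named the 12 genes with the largest rise and the 12 with the largest fall among called features with 1 gene, with at least 5 of 6 recovery arrays on the same side of the light-adapted mean. It also named LHCB1 members and a few dark- and light-responsive genes whatever their result, of which LHB1B2 was the one tested on a feature with 1 gene. The 18 gene lists covered light-harvesting antenna, photosystem I, photosystem II, photosynthetic electron transport and ATP synthase, the Calvin-Benson cycle, tetrapyrrole and chlorophyll synthesis, carotenoid and plastid isoprenoid synthesis, light stress and plastid antioxidants, plastid ribosomal proteins, photorespiration, starch and sugar metabolism, and nitrogen and sulfur assimilation. They also covered plastid import, chaperones and proteases, plastid transcription, the thioredoxin system, dark-inducible and sugar-starvation genes, light signalling and the circadian clock, and markers of other organs and cell types. A list was to be tested with limma's camera from 5 measured members. None reached that number in the main fit, so the planned list test was run on 0 lists there.

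Arrays 1 and 2, 3 and 4, and 5 and 6 of each group had like totals and lay together on the leading principal components. Spearman correlations of deposited intensities across features ran from 0.791 to 0.939 within such pairs of light-adapted arrays and from 0.788 to 0.830 within those of recovery arrays. They overlapped those between pairs of the same group, 0.750 to 0.836 and 0.763 to 0.798, and arrays 5 and 6 lay within the overlap in both groups. Each such pair is called a set below, a division chosen after seeing the data and not given by the labels. The fit was repeated on the mean of each set, 3 against 3. Same-numbered arrays of the 2 groups were checked for pairing: their deviations from the group means correlated with r between 0.108 and 0.193 for the 6 pairs across 1429 features, and all 12 arrays correlated best with the array of their own number. On the evidence of the values and not of the labels, the numbers were taken to pair the arrays. The unpaired fit of 6 arrays against 6, planned in advance, was kept as the main one. SEs and adjusted p-values below come from it unless another fit is named.

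The fit was tested on simulated data with 200 of 2364 features changed. With independent arrays, 6 arrays against 6 recovered 30% of the 2-fold and 63% of the 4-fold changes, and 3.12% of the calls were false. When the arrays of a set shared their deviations with the correlation of 0.482 estimated here, 27.6% of the calls of the 6 against 6 fit were false, 45 of 163. The fit on 3 set means then recovered 1% of the 2-fold and 32% of the 4-fold changes, with 3 false calls of 36. Alternatives covered the scaling, dim features, zeros, the replicate block, the test, array weights, each array left out in turn and the sets.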

Results

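The series compared light-adapted wild-type plants with plants that had spent 1 h in darkness and then recovered in light for 2 h per the titles and descriptions, or 1 h per the source names. No sample was taken at the end of darkness, so effects of darkness and of the return to light cannot be told apart. Below, rose and fell mean higher and lower in recovery than in light-adapted plants. Expression was measured on 12 arrays, 6 per group, as intensities of 3439 features, taken as linear. Exact zeros made up 19.96% ± 1.70 of the features on the light-adapted arrays and 25.6% ± 2.21 on the recovery arrays (SD, n = 6 each).

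In recovering plants, the transcripts of IAA31, a member of the Aux/IAA family of auxin-response repressors, and of the chloroplast ribosomal protein L29 gene (AT5G65220) fell far below their level in light-adapted plants. CYN, which encodes cyanase, the calmodulin-like gene CML41 and the salt-induced gene SIS rose. The deposited intensity of IAA31 was 1.90 ± 0.284 in light-adapted and 0.0552 ± 0.0122 in recovery arrays (SD, n = 6 each), and that of CML41 was 0.182 ± 0.0524 and 0.698 ± 0.139. Of 2364 features tested, 438 were higher and 435 lower in recovery at an adjusted p under 0.05 in limma, 873 in all, and 726 of these changed at least 2-fold. Features with 1 gene made up 154 of the calls, 66 higher and 88 lower.

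The 12 largest rises among named genes lay between 2.53 and 3.51 on the log2 scale. AT4G13550, which encodes a heat-inducible lipase, rose by 3.31 ± 0.227 (SE, limma adjusted p = 7.12e-07) and was higher in 6 of 6 recovery arrays. SIS rose by 2.96 ± 0.223 (limma adjusted p = 1.36e-06), CYN by 3.04 ± 0.461 (limma adjusted p = 0.000263) and CML41 by 2.54 ± 0.240 (limma adjusted p = 7.17e-06), each in 6 of 6 recovery arrays. With the replicate number as a block, the limma adjusted p-values were 0.000148 for AT4G13550, 0.000414 for SIS, 0.00127 for CYN and 0.000435 for CML41. With 3 set means they were 0.00469, 0.00469, 0.0248 and 0.00533 in that order. AT1G17160, a gene for ribokinase, rose by 2.60 and AT2G35390, which encodes a ribose-phosphate pyrophosphokinase, by 2.85. The other rises were AT4G27250 at 3.51, AT2G37750 at 3.31, AT4G08280 at 2.90, AT5G62550 at 2.90, AT4G13680 at 2.77 and AT4G04370 at 2.53. On the deposited scale all 12 rises were smaller, between 1.70 and 2.90, and 8 of them moved by more than 1.5-fold, among them SIS, AT4G27250 at 2.82, AT2G35390 at 2.09 and AT4G08280 at 2.00. After median centring the 12 rises ran from 2.70 to 3.90. AT4G27250 rested in part on 1 low light-adapted array, light-adapted replicate 2, without which its difference was 2.53, and AT5G62550 was at 2.13 without the same array. AT5G62550 lay near 0 in both groups, at mean intensities of 0.0107 and 0.0246, and was at 1.72 when zeros were kept with a pseudocount, a setting chosen after the data were seen. The sizes of other rises are also uncertain because the light-adapted mean was near 0. It was 0.0214 for AT4G13680, 0.0442 for AT2G37750, 0.0466 for AT4G08280 and 0.0651 for AT4G27250, each above 0 on 5 light-adapted arrays. For AT2G35390, AT4G04370 and SIS it was 0.0721, 0.0729 and 0.0873, with 6 arrays above 0. AT4G13680 was at 3.36 without light-adapted replicate 6. AT4G13680 lost its call with the replicate number as a block (limma adjusted p = 0.0583), and AT5G62550 lost its call on the deposited scale (limma adjusted p = 0.0863).

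The 12 largest falls ran from -3.35 to -4.74. IAA31 fell by 4.59 ± 0.197 (SE, limma adjusted p = 1.55e-08), AT2G46630 fell by 4.53 ± 0.182 (limma adjusted p = 1.55e-08) and AT5G65220 fell by 3.42 ± 0.302 (limma adjusted p = 4.69e-06), each lower in 6 of 6 recovery arrays. With the replicate number as a block, the limma adjusted p-values were 3.97e-05 for IAA31, 6.03e-05 for AT2G46630 and 0.000351 for AT5G65220. With 3 set means they were 0.00187, 0.00187 and 0.00453 in that order. AT1G01250, which encodes an AP2/ERF family transcription factor, fell by 3.35. AT3G09250 fell by 4.74 ± 0.597 (limma adjusted p = 0.000101) and was lower in 5 of the 5 recovery arrays where it was above 0. Its recovery intensities were near 0, at a mean of 0.0253, so the size of its fall is uncertain (-4.21 without recovery replicate 3). The remaining falls were AT1G06730 at -4.47, AT5G26850 at -4.03, AT3G44570 at -3.93, AT5G55570 at -3.74, AT3G24190 at -3.47, AT4G18180 at -3.40 and AT4G07670 at -3.36. The sizes of other falls are uncertain for the same reason, with mean recovery intensities of 0.0170 for AT5G55570, 0.0202 for AT3G44570 and 0.0375 for AT3G24190. The same holds for AT4G07670 at 0.0432 and AT1G01250 at 0.0680, each above 0 on 5 recovery arrays. IAA31, at 0.0552, and AT5G65220, at 0.0718, were also low but above 0 on 6 recovery arrays. On the deposited scale all 12 falls were larger, from -3.85 to -5.44, and after median centring they ran from -2.87 to -4.41. The difference of AT3G24190 was -2.82 without light-adapted replicate 6, that of AT3G44570 -3.34 without recovery replicate 4 and that of AT4G18180 -4.11 without light-adapted replicate 1. AT5G55570 was at -2.64 with the pseudocount.

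**Figure D1:**
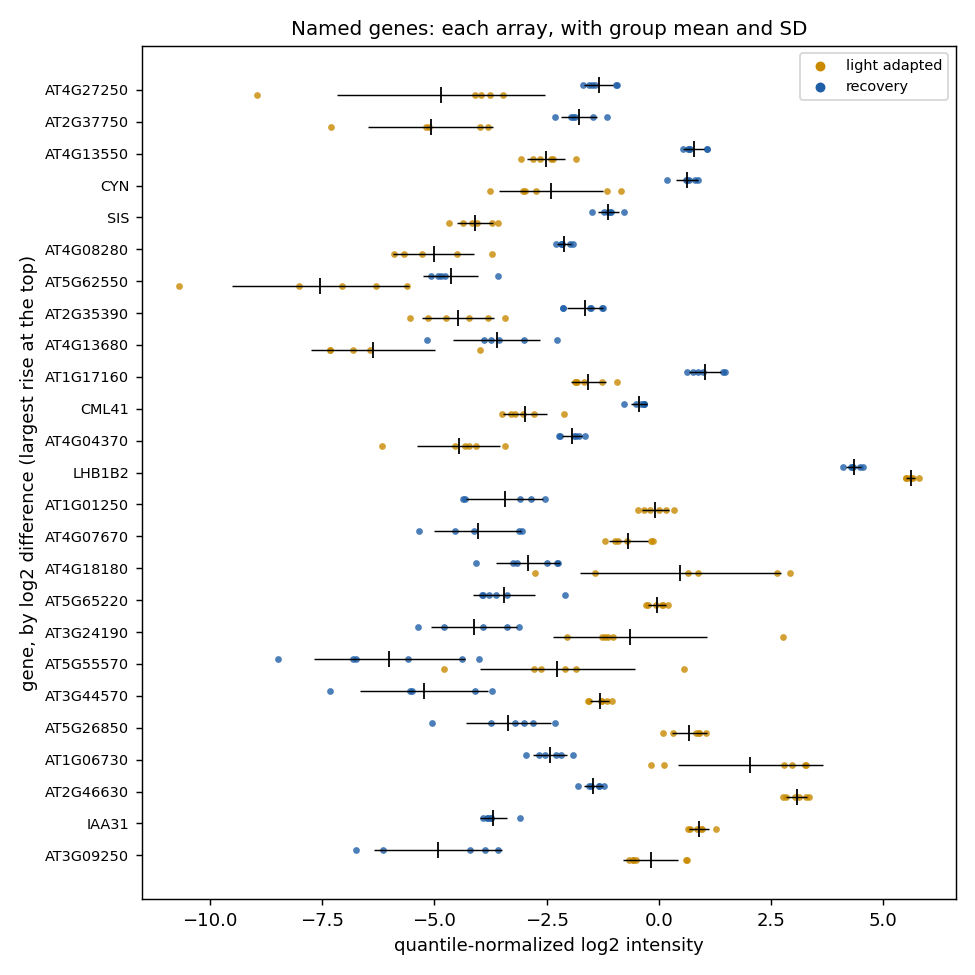
Quantile-normalized log2 intensity of the 25 genes named by the rule, on the horizontal axis, for each light-adapted (orange) and recovery (blue) array above 0, with ticks and bars for group mean and SD. IAA31 and AT2G46630 show no overlap between the groups, while AT4G27250 has 1 light-adapted array far below the others.

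Genes of the lists fixed in advance were matched only on features with 1 gene, and 14 were tested. Members on the 870 features with several genes or the 1877 not named could not be counted. A low count therefore does not show that a list was missing from the array. Of the 3 photosystem II members, PSBW rose by 1.48 ± 0.212 (SE, limma adjusted p = 0.000174), in 6 of 6 recovery arrays, and was at 2.91 after median centring, while PSB27 at -1.35 (limma adjusted p = 0.0736) and PSBY at 0.19 did not pass. After median centring PSBY gained a call, at 1.39 (limma adjusted p = 0.000111), and PSB27 was at -0.44. PRK, the phosphoribulokinase of the Calvin-Benson cycle and the member of that list that could be tested, fell by 1.63 ± 0.174 (limma adjusted p = 1.86e-05), and median centring of the arrays took the call away, at -0.50. The antenna gene LHB1B2 (LHCB1.5) fell by 1.28 ± 0.157 (limma adjusted p = 5.62e-05). It lost the call in the unpaired fit on the deposited scale, at -0.77 (limma adjusted p = 0.0551), and its sign turned after median centring, at 0.22. Its deposited intensity was lower in recovery in every same-numbered pair of arrays, by least in those numbered 3, at 48.7 light adapted and 37.8 recovery. No paired fit was run on the deposited scale. PSAN of photosystem I did not pass at -0.29. It was near no change on the deposited scale, at 0.017 (limma adjusted p = 0.961), and was called as a rise after median centring, at 1.01 (limma adjusted p = 0.000872).

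Both measured thioredoxin system genes rose: NTRC, the NADPH-dependent chloroplast thioredoxin reductase, by 1.95 ± 0.260 (SE, limma adjusted p = 0.000104) and FTRB, a subunit of ferredoxin-thioredoxin reductase, by 0.89 ± 0.276 (limma adjusted p = 0.0231). On the deposited scale NTRC was called at 0.93, and FTRB lost its call, at 0.48. NTRC was dim, at mean intensities of 0.0547 in light-adapted and 0.103 in recovery arrays, so the size of its rise is uncertain. Of the 3 plastid ribosomal protein genes tested, AT5G65220 fell, PRPL17 (AT3G54210) rose by 1.41 ± 0.491 (limma adjusted p = 0.0398) and PRPL5 (AT4G01310) did not pass at 0.63. PRPL17 lost its call on the deposited scale, at 0.81, and without light-adapted replicate 2 or any of recovery replicates 1, 3, 4, 5 and 6, at 1.29 to 1.45. The tetrapyrrole genes CHLM, at 0.34, and CHLP (AT1G74470), at 0.30, did not pass, nor did the sulfate assimilation gene APS4 at 0.74. On the deposited scale the signs of PRPL5, CHLM and APS4 turned, without a call. After median centring CHLP, at 1.38 (limma adjusted p = 0.000411), and PRPL5, at 0.80 (limma adjusted p = 0.0380), gained calls. Counted over all features tested, 4 of the 14 members rose, 3 fell and 7 did not pass. When adjusted over the list alone, each within its own list, 10 passed, with APS4, PSB27 and PRPL5 added to the calls, and over the 14 members pooled the count was 7. The lists had 1 to 3 tested members, so adjustment within them does little. For APS4, alone in its list, and for PRPL5 it left the unadjusted limma p of 0.0480 and 0.0332.

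Of the other fixed lists, 10 had 0 tested members: electron transport and ATP synthase, carotenoid and plastid isoprenoid synthesis, light stress, photorespiration, starch and sugar metabolism, plastid import, plastid transcription, dark-inducible genes, light signalling and clock, and markers of other organs. The 6 photosynthesis members as a group, a grouping chosen after the data were seen, had a median difference of -0.78, which turned to 0.62 after median centring. Their camera p in limma was 0.220, and 0.232 with an estimated correlation, which does not set the group apart from the other features. Limma's fry, a rotation test of the group and not an exact test, gave p = 2.77e-05 for a shift on balance downward. All 14 members together had a median of 0.32 and a camera p of 0.720 (direction up, 0.703 with an estimated correlation), with a mean of -0.0016 and a fry p of 0.128 (direction down).

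**Figure D2:**
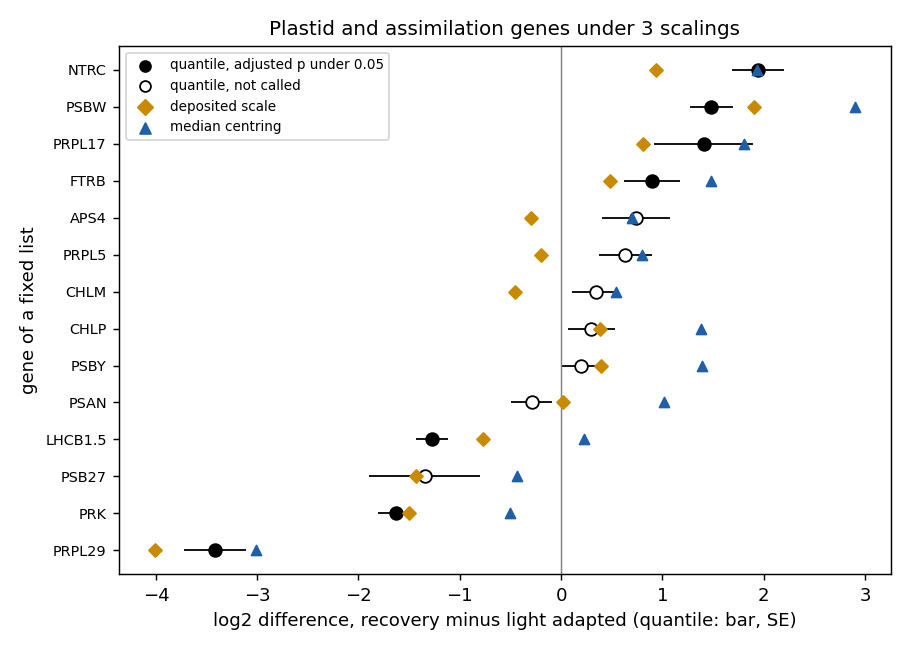
Log2 difference, recovery minus light adapted, on the horizontal axis for the 14 tested members of the fixed lists, as quantile normalized (circles with SE, filled where called), on the deposited scale (orange diamonds) and after median centring (blue triangles). NTRC and PSBW lie above 0 and PRPL29 (AT5G65220) and PRK below 0 in all 3 scalings, while LHCB1.5 lies on either side.

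The scaling moved the balance of higher and lower calls. On the deposited scale 226 features were higher and 870 lower, with a median log2 difference of -0.82 over all features tested, and after median centring 646 were higher and 323 lower, with a median of 0.19, against -0.038 in the quantile-normalized values. Median intensity was 0.0919 ± 0.0145 in the light-adapted and 0.0373 ± 0.00148 in the recovery arrays (SD, n = 6, exact permutation p = 0.00216, the smallest the possible splits can give). Summed intensities were 2703 ± 439 and 2722 ± 465 and did not pass the exact permutation test (p = 0.814).

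**Figure D3:**
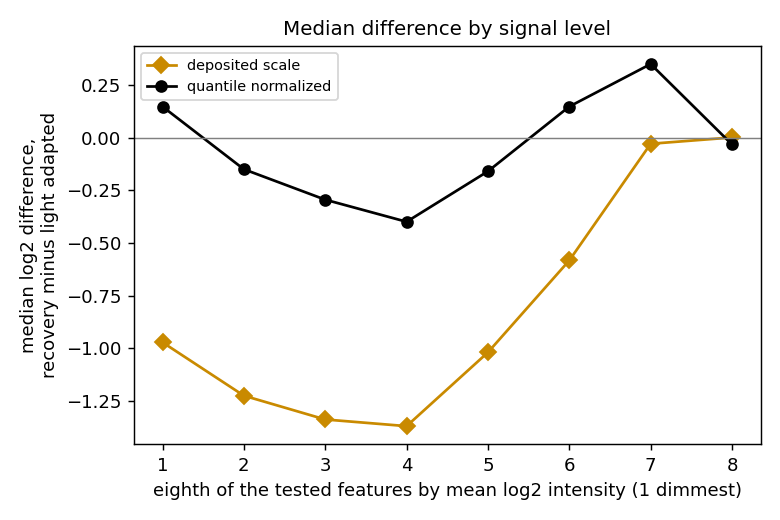
Median log2 difference, recovery minus light adapted, for the tested features in eighths of mean log2 intensity from dimmest (1) to brightest (8), on the deposited scale (orange) and quantile normalized (black). The deposited-scale median was -1.37 in the fourth eighth and 0.0018 in the brightest.

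Arrays of a set had like totals and principal component scores, although their correlations overlapped those between sets, and it is not known whether 6 arrays stand for 6 samples or 3. In 1 simulation with arrays that shared their set and 200 of 2364 features changed, 45 of 163 calls of 6 arrays against 6 were false, 27.6%. With nothing changed there were 13 calls. The false share depends on how many features change, so it cannot be carried over to the 873 calls made here. With the mean of each set, 3 against 3, limma called 199 features higher and 206 lower, 405 in all, and 402 of these were among the 873 with the same sign. AT4G27250 (limma adjusted p = 0.0849, with a larger difference), AT5G62550 (2.76, 0.0738), AT4G18180 (-3.40, 0.0975), PRPL17 (1.41, 0.148) and FTRB (0.89, 0.138) lost their calls in that comparison, where the other 4 differences were close to those of 6 arrays. Leaving out a whole set ended the calls of AT4G13680 (2.07 without set 1), AT5G55570 (-3.48 without set 2), AT4G18180 (-1.86 without set 2, -3.36 without set 3), FTRB (0.94 without set 1) and PRPL17 (1.76 without set 2, 1.46 without set 3). It kept the calls but moved the differences of AT1G06730 (-3.78 without set 2, -5.33 without set 3), CYN (3.65 without set 3), AT4G27250 (2.64 without set 1), AT5G55570 (-4.57 without set 1) and AT4G18180 (-5.03 without set 1). With the set within its group as a random block, AT5G62550 (2.83), AT5G55570 (-3.74), AT3G24190 (-3.53), PRPL17 (1.41) and FTRB (0.89) lost their calls, again with differences close to those of 6 arrays. Called with the same sign with 6 arrays, with 3 sets, on the deposited scale and after median centring were 353 features, 164 higher and 189 lower. Of the 25 genes named by the rule, 21 were among them, 10 higher and 11 lower.

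The groups separated along the first principal component, which held 49.5% of the variance. Its scores were -26.7 ± 3.94 in light-adapted and 26.7 ± 1.19 in recovery arrays (SD, n = 6, exact permutation p = 0.00216, the smallest the possible splits can give). Counted as 3 sets against 3, no exact test could go below 0.1. On the second component, with 10.8% of the variance, light-adapted scores had an SD of 18.7 and recovery scores 4.77.

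**Figure D4:**
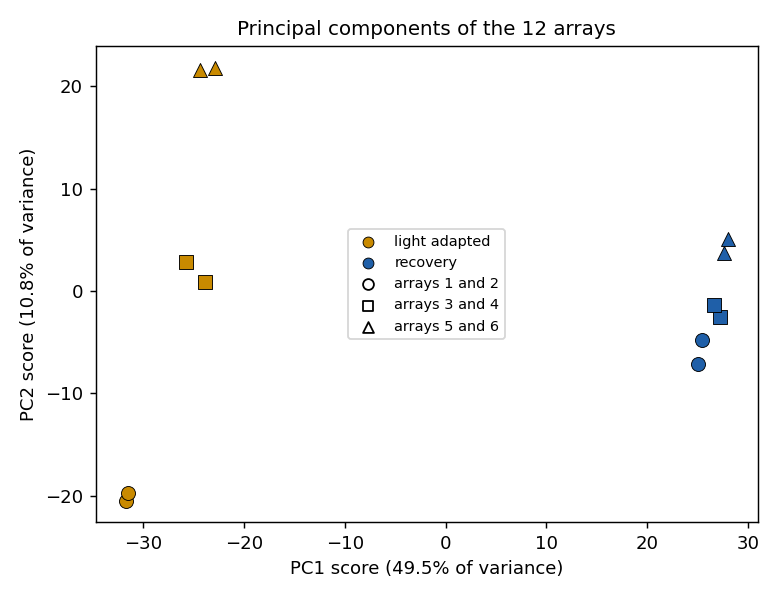
Scores of the 12 arrays on the first 2 principal components of the quantile-normalized log2 values (horizontal and vertical axes, with their percent of variance), coloured by group and with 1 marker shape per set of arrays. Light-adapted arrays lie left and recovery arrays right, and the light-adapted sets spread along the vertical axis from -20.5 to 21.8.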

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

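The tests of sets, position, a scale factor, a constant background and a growing offset below were chosen only after the results were seen.

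Chance was weighed first as the source of the called features. Of 100 splits of the 12 arrays into 6 and 6, only 1, the real one, gave as many as 873 calls. The highest of the other splits gave 0, which argues against chance if the 12 arrays are separate samples. Those splits mix the groups and break up the sets, which by itself leaves few calls. If each set is 1 sample, chance cannot be excluded, since an exact test of 3 sets against 3 cannot go below 0.1. With the numbers taken to pair the arrays, the real split was also set against the 32 splits that part all 6 pairs. The highest other of these gave 1 call, and the 4 that keep the sets whole are too few for a share under 0.05. Calls were counted in the unpaired fit, and the other splits again mix the groups. That by itself leaves few calls, so this comparison adds no support. Repeat readings counted as separate samples could inflate the count, and with 3 set means against 3 it was 405, 17.1% of the features tested, which argues against this as the whole source, while the other calls stay open to it. Position on the array was tested by centring each run of 96 feature numbers, which gave 882 calls, 688 of them among the 873 with the same sign. What the sets are, and the biological explanation, a difference between recovering and light-adapted plants, stay open, since the labels do not describe the replicates.

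The excess of lower calls on the deposited scale was weighed as a second pattern. A single scale factor between the groups is argued against by the median log2 difference, which was -1.22 in the dimmest 50% of the features and -0.0053 in the brightest 25%, a gap of -1.21 ± 0.0790 (bootstrap SE). A constant background in the light-adapted arrays would give a like intensity difference at each level, but the largest was 2.60 times the smallest over the second to sixth eighths (95% bootstrap interval 2.11 to 3.33). For an offset that grows with the level the values point both ways. The median intensity difference grew from -0.0184 in the dimmest eighth to -0.109 in the fifth. It was -0.0281 in the brightest 2, a gap of 0.0812 to the fifth (95% bootstrap interval 0.0147 to 0.117). The fifth eighth had the largest difference and was picked after the results were seen. The normalization of the deposited values is unknown and may have evened out the brightest features, so this test cannot decide. Scaling by the total without the 11 features at the ceiling left the median at -0.77. This cannot decide whether the brightest features were the source. Levels above the ceiling are not known, and other bright features stayed in the total. A lower level of many weakly expressed transcripts in recovering plants stays open and untested. The background correction of the arrays is not known, and a difference in it between the groups was not tested either.

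An array far from the other arrays of its group was found in 10 of 80 groups of values, where chance gives about 1 in 20, or 4. The values below are normalized log2 intensities. In AT4G27250, light-adapted replicate 2 was at -8.97 against -4.09 to -3.48 for the others, and the difference between groups was 2.53 without it. In AT4G13680, light-adapted replicate 6 was at -3.99 against -7.33 to -6.43, and the difference was 3.36 without it. In AT3G24190, light-adapted replicate 6 was at 2.77 against -2.04 to -1.01, and the difference was -2.82 without it. In PRPL17 (AT3G54210), light-adapted replicate 1 was at -5.01 against -2.65 to -1.86, and the difference was 0.95 without it. In NTRC, light-adapted replicate 1 was at -5.74 against -4.81 to -4.36. CHLP (AT1G74470) had light-adapted replicate 6 at 0.39 against 1.18 to 1.60, and AT5G62550 had recovery replicate 1 at -3.58 against -5.08 to -4.77. IAA31 had recovery replicate 2 at -3.08 against -3.92 to -3.73, and AT5G65220 had recovery replicate 6 at -2.09 against -3.93 to -3.39. PSB27 had recovery replicate 6 at -1.08 against -0.37 to 0.017, and its difference did not pass without that array, at -1.19 (limma adjusted p = 0.131). It passed, at -1.78, without light-adapted replicate 6, which was not flagged.

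Some features left out of the test because a whole group was at 0 carried a signal in the other group, while 103 were at 0 on all 12 arrays. Above 0 on all 6 light-adapted arrays and listed at 0 on all 6 recovery arrays were 13 features, and the reverse held for 2. The 13 include AT2G03200, at a mean of 0.140, AT3G52550 at 0.122, AT3G56290 at 0.111, AT3G50350 at 0.106 and AT3G29410 at 0.0564 in the light-adapted arrays, named here after their values were seen. These means lay near the light-adapted median intensity of 0.0919, and the lowest AT3G50350 value was 0.00203. Recovery arrays had more zeros on average, 25.6% against 19.96% of the features. The median log2 difference on the deposited scale was -1.22 in the dimmest 50% of the features tested. Whether the excess of 13 over 2 goes beyond this shift of dim features was not tested. A listed 0 therefore does not show that a gene was switched off.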

How the results depend on the processing

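The settings with sets, the pseudocount, centring on tested features and features above 0 on all arrays were chosen after seeing the data. The planned pseudocount was not run because the 5th percentile of all values is 0, and the planned list test had 0 lists in the main fit. With the added pseudocount 1 list, plastid ribosomal proteins, had 6 members and a camera p in limma of 0.640. The count of 873 stayed within 1.5 times of itself except with 3 set means (405, with 199 higher and 206 lower). Higher and lower calls moved on the deposited scale to 226 and 870, and lower calls were 281 without set 1 and 284 without set 2, where fewer features were tested. Leaving out 1 array gave 781 to 858 calls, 397 to 434 higher and 376 to 435 lower, and a first component of 48.4% to 51.1%. With the replicate block there were 832 calls, 406 higher and 426 lower. The block ended the call of AT4G13680 and gave PSB27 one, which it lacked with 3 set means or the set as a random block, and it changed no other call of a named gene or list member. The set as a fixed block gave 976 calls, and the set within its group as a random block 632. With the fixed set block FTRB, PRPL17 and PSB27 were called (limma adjusted p = 0.00942, 0.0178 and 0.0339). Signs turned on the deposited scale for PSAN (0.017), APS4 (-0.30), CHLM (-0.46) and PRPL5 (AT4G01310, -0.20). Median centring over all measured or only the tested features turned LHB1B2 (0.22 and 0.16), PSAN (1.01 and 0.95) and the median of the 6 photosynthesis members (0.62 and 0.55), and PSBY turned without set 3 (-0.016). Against the deposited scale, median centring raised the difference of each gene above 0 on all 12 arrays by the same amount. LHB1B2, PSAN, PSBY and CHLP had mean intensities above the medians of the brightest eighth of features. The median difference of that eighth on the deposited scale was 0.0018. Their turns and gained calls after centring thus rest on a shift not seen at that level. The cause of the other turns was not tested. The 25 genes named by the rule were kept on their side of the threshold in 626 of 642 comparisons, lost it in 14 and turned in 2. Settings in which a gene was no longer tested were left out of these comparisons. All but LHB1B2 were picked for large called differences in these same arrays, so the high share is no independent check. For the 12 other list members, 284 of 324 stayed, 18 lost the call, 15 gained it and 7 turned. Values at 0, up to 28.6% of an array, limit what dim features show.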

Other observations

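Beyond the genes named by the rule and the members of the fixed lists, 7 genes with a symbol in the reference table were called with the same sign with 6 arrays, with 3 sets, on the deposited scale and after median centring, a selection made after the data were seen. THIC, which acts in the synthesis of the pyrimidine part of thiamine, rose by 2.50 ± 0.158 (SE, limma adjusted p = 3.92e-07), and OTP70, an organelle transcript processing gene, rose by 1.84 ± 0.201 (limma adjusted p = 2.32e-05). PPDK, the pyruvate orthophosphate dikinase, fell by 2.40 ± 0.463 (limma adjusted p = 0.00147) and ATSPS4F, a sucrose-phosphate synthase gene, fell by 1.74 ± 0.251 (limma adjusted p = 0.000181). CML30, a calmodulin-like gene as CML41 is, fell by 1.75, PAC (PALE CRESS) fell by 1.18, and SPL (SPOROCYTELESS) fell by 3.00. With 3 sets the differences were 2.50 ± 0.291 for THIC, 1.84 ± 0.304 for OTP70, -2.40 ± 0.508 for PPDK, -1.74 ± 0.393 for ATSPS4F, -1.75 ± 0.319 for CML30, -1.18 ± 0.306 for PAC and -2.69 ± 0.691 for SPL (limma). On the deposited scale OTP70 was at 1.13, SPL at -4.00, PPDK at -3.11 and THIC at 1.99, and after median centring CML30 was at -0.83, ATSPS4F at -0.98 and PAC at -0.71.

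Some features reached the ceiling of 100. Feature 1431, whose annotation lists several genes, was at the ceiling on all 6 recovery arrays and at a mean of 8.93 on the light-adapted arrays, with a range from 6.86 to 12.4. Feature 3656, not named in the annotation, was at the ceiling on all 6 light-adapted arrays and at 41.4 on the recovery arrays, with a range from 29.3 to 60.3. Differences of such features are bounds.

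The log2 differences varied with the feature number. Runs of 96 feature numbers accounted for 6.27% of their variance across features, against a 95th percentile of 2.65% in 1000 shuffles (permutation p = 0.001, the smallest these shuffles can give). The layout of the array is not given in the sources used here.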
